A study of Mus musculus with 8 samples.

How the data were processed

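RNA sequencing was analysed from 8 samples of sorted spinal cord neutrophils, 4 taken at ZT1 and 4 at ZT13 from mice with EAE. Per the labels' protocols, cells were sorted into a stabilising reagent and RNA was reverse transcribed and amplified with the SMART-Seq v4 kit. Libraries were made with Nextera XT, which does not mark the strand, and single reads of 50 bases were generated on an Illumina sequencer. The labels place all samples in 1 batch. The labels speak of cells per mouse and give no animal identifiers, so that each sample was taken as a separate mouse. If samples shared an animal, p-values would measure only the spread between these samples.

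The authors deposited 1 table of raw counts per gene, with 23369 genes named by Ensembl identifiers. Per the submitters' processing notes the tools were FastQC, STAR 2.7.10b, featureCounts, Subread 2.0.3 and DESeq2 1.46.0 with build GRCm38. Their roles, the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads of near-identical paralogs and of overlapping or antisense genes can therefore not be told apart. Of the identifiers, 22222 matched the GENCODE M21 annotation of GRCm38 when version numbers were ignored, and 17 had the same version; the 1147 without a match held 0.125% of the counts. Gene names, coordinates, transcript lengths and GC content were taken from that annotation, which is not the release behind the counts. The table holds 14163 of 22028 protein-coding genes of that annotation and 7 of 13 mitochondrial mRNAs; the others were not analysed here, and the rule that kept a gene is not given in the sources used here. Table columns were assigned to samples by the library names in the labels, and no column was left unused.

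Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total count 15), which kept 12610 genes, TMM normalization factors, robust quasi-likelihood fits and F-tests of ZT13 over ZT1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors, and log2 CPM values use a prior count of 2. Totals of 46152067 to 67873023 counts per library put 3 counts, the limit that a count of 0 allows, at 0.0442 to 0.0650 CPM, and the biological coefficient of variation was 0.498. These limits cover counting error only. For genes above a few CPM the spread between samples, not depth, set the precision. Exact two-sided permutation tests over the 70 assignments of 4 and 4 libraries were used for single values per library.

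Gene lists, 42 in all, were tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The lists, the tests, the rule for named genes and the alternatives, except those named as chosen later, were set before the data were examined. By that rule the text names the 10 genes per direction with the largest change among those past the threshold with 8 or more CPM in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes. Where fewer pass, they are filled up to 10 with the smallest unadjusted p among genes of 8 or more CPM (here all of them). It also names all tested clock genes of the morning and evening arms, up to 4 members of any other list with the smallest p, the most abundant and the smallest-p member of each list of another cell type, the sort markers, and Ddx3y as a check of sex. Xist, also in the rule, was not analysed here. Not every gene the rule allows is printed, and some are not reported here.

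Alternatives to the normalization (DESeq2 size factors, upper-quartile factors, library totals), to the filter (none; 5 or more CPM in 4 samples), to the test (DESeq2 1.42.0, limma-voom with and without sample quality weights, a fold change above 1.5, an adjusted threshold of 0.1), to the samples (each left out in turn) and to the design (the replicate number as a block, taken from sample titles or from library names) were run. The procedures were tested on simulated data drawn from the means, library sizes and gene-wise dispersions of the 12610 genes in 3 runs per setting. With 200 genes changed 2-fold, edgeR recovered 33.5% of them with 3.33 false calls on average and DESeq2 47.2% with 45.7; with 200 genes changed 4-fold, edgeR recovered 65.0% and DESeq2 74.3%.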

Results

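Neutrophils were sorted as CD45+CD11b+Ly6G+ cells from the spinal cords of C57BL/6N mice with experimental autoimmune encephalomyelitis (EAE), an induced autoimmune inflammation of the central nervous system that serves as a mouse model of multiple sclerosis. Their RNA was sequenced at 2 zeitgeber times (hours after lights-on), ZT1 (n = 4) and ZT13 (n = 4). The single comparison of the design asks how the transcriptome of neutrophils in the inflamed spinal cord differs between the start of the light phase and the start of the dark phase. The total count per library ranged from 46152067 to 67873023. The most abundant transcripts were those of neutrophil granule and cytosolic proteins, led by Ngp with 3.96% of all counts, Ltf with 3.39%, S100a9 with 3.38% and S100a8 with 3.11%. The genes of the sort markers were present in both groups. Itgam (CD11b) stood at 482 ± 16.8 CPM (counts scaled to library size; mean ± SD, n = 4) at ZT1 and 488 ± 14.9 at ZT13, and Ptprc (CD45) at 1816 ± 144 and 1602 ± 56.0. Ly6g stood at 369 ± 108 and 485 ± 24.2 CPM, with a log2 fold change of 0.39 ± 0.18 (SE) for ZT13 over ZT1 that was not past the threshold (edgeR adjusted p = 0.548). The Y-linked gene Ddx3y had between 2630 and 4760 counts in the 8 libraries, so no library came from female mice alone.

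The ZT13 libraries held fewer detected genes. Genes with 1 or more counts numbered 16891 ± 815 at ZT1 and 14909 ± 766 at ZT13, with every ZT13 library below every ZT1 library (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give). The 10 most abundant genes took 19.1 ± 1.20% of the counts at ZT1 and 22.7 ± 1.29% at ZT13 (exact permutation p = 0.0286), again without overlap. Total counts did not separate the groups (exact permutation p = 0.257). The separation by detected genes was narrow, with 15751 in ZT13 replicate 2 and 15760 in ZT1 replicate 4, the library with the largest total. Genes with 10 or more counts overlapped between the groups (13158 ± 274 and 12350.5 ± 494, exact permutation p = 0.0571). Thinned to equal totals, 1 ZT13 library lay above the lowest ZT1 library in detected genes (exact permutation p = 0.0571). On principal components of log2 CPM, the first component (30.4% of the variance) set ZT13 replicate 3 apart from the other 7 libraries, and this library also had the fewest detected genes (13945). Components 2 (19.1%) and 3 (18.2%) set ZT13 replicates 1 and 4 apart from the others. On these 3 components 3 of the 4 ZT13 libraries thus stood apart, while the 4 ZT1 libraries lay closer together. By chi-square per gene between pairs of libraries ZT1 was not the tighter group, with 67.7 to 206.5 within ZT1 and 81.3 to 148.4 within ZT13. No pair of libraries agreed within sampling noise, and all 8 were counted as separate samples.

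**Figure D1:**
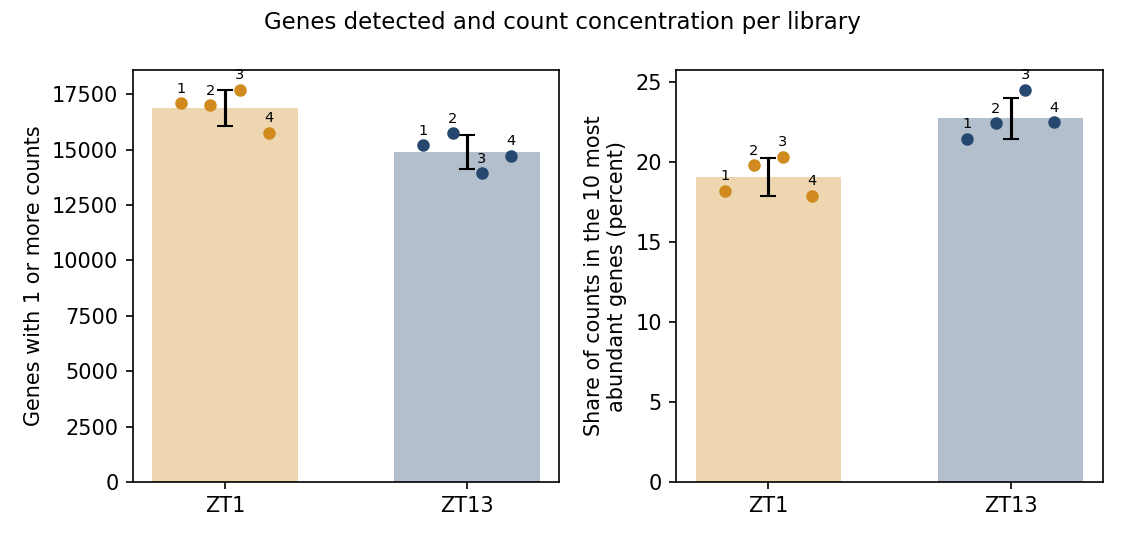
Genes with 1 or more counts (left) and the share of counts in the 10 most abundant genes in percent (right), for 4 libraries of each time point. Bars are means, error bars SD, points single libraries numbered by replicate; the ZT13 libraries lie between 13945 and 15751 detected genes and the ZT1 libraries between 15760 and 17701.

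Among single genes, those with the smallest p and higher values at ZT13 included Klf13, a Krüppel-like transcription factor, at 94.4 ± 8.29 CPM at ZT1 and 164 ± 28.7 at ZT13 (log2 fold change 0.79 ± 0.13 SE). Crispld2 stood at 200 ± 42.7 and 371 ± 51.2 (0.89 ± 0.17) and Rbm3, a cold-inducible RNA-binding protein, at 51.6 ± 4.43 and 77.1 ± 5.08 (0.58 ± 0.11). Those with lower values at ZT13 included Cxcl9, an interferon-gamma-inducible T cell chemoattractant, at 14.4 ± 12.1 and 0.247 ± 0.247 CPM (-5.82 ± 1.12). Gbp5, an interferon-inducible GTPase, stood at 17.7 ± 11.99 and 0.990 ± 0.735 (-4.17 ± 0.74). None of these differences was past the threshold. Of 12610 genes tested with the quasi-likelihood test of edgeR, 0 had a Benjamini-Hochberg adjusted p under 0.05, while 1160 stood at an unadjusted p under 0.05 and DESeq2 called 256. The smallest adjusted p in edgeR was 0.246. Of the 1160 genes, 548 were higher at ZT13 (47.2%) and 612 higher at ZT1. Chance would give 630 on average, with a wider spread where genes vary together. Other splits of the 8 libraries into 4 and 4 gave a median of 402.5 and at most 1124. Every such split mixes the time points within its groups, where a difference between them would add to the spread. The share higher at ZT13 was 34.0% with library totals in place of TMM factors, 49.9% with DESeq2 size factors and 55.3% with upper-quartile factors. The groups did not overlap for 714 genes (5.66%), where chance gives 2.86%. Of the 256 genes called by DESeq2 on the same counts, 91 were higher at ZT13 and 165 higher at ZT1. Of these, 51 had no count in the 4 ZT13 libraries and 0 had none in the 4 ZT1 libraries. Without the 75 called genes that had a library at 0, 90 were higher at ZT13 and 91 higher at ZT1. On simulated counts with no change, DESeq2 made 21.3 calls on average and edgeR 0.667.

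The 19 genes named here for their small p are past no threshold in edgeR, and all 19 separated the 4 libraries of one time point from the 4 of the other. With higher values at ZT13 these were Klf13, Rbm3, Crispld2, Scrg1, Iqsec1, the ribosomal protein gene Rpl6, Msl1, Rit1 and Ppia, with log2 fold changes between 0.43 (Ppia, cyclophilin A) and 0.95 (Scrg1). With higher values at ZT1 they were Ubap2, Adnp2, Gbp5, Ap2b1, Nxf1, Cxcl9, Edem1, Dhx29, Zswim4 and Ccnl1. Apart from Cxcl9 and Gbp5 the latter had log2 fold changes between -1.17 (Ubap2, 22.4 ± 4.14 against 9.94 ± 0.486 CPM) and -0.40 (Edem1, an endoplasmic reticulum degradation factor, 429 ± 7.97 against 324 ± 23.5 CPM). Adjusted p-values of the 19 genes ran from 0.246 to 0.315 in edgeR and from 4.58e-08 to 0.00514 in DESeq2. On GRCm38, Klf13 (ENSMUSG00000052040.11) lies on chromosome 7 from 63886351 to 63938915 and Ubap2 (ENSMUSG00000028433.15) on chromosome 4 from 41194313 to 41275144. Gbp5 (ENSMUSG00000105504.5) lies on chromosome 3 from 142493978 to 142522344 and Cxcl9 (ENSMUSG00000029417.10) on chromosome 5 from 92321347 to 92328079. The annotation lists all of these as protein-coding genes. Gbp5 belongs to a family of similar genes whose reads the counting could have split, and its values are uncertain to that extent.

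**Figure D2:**
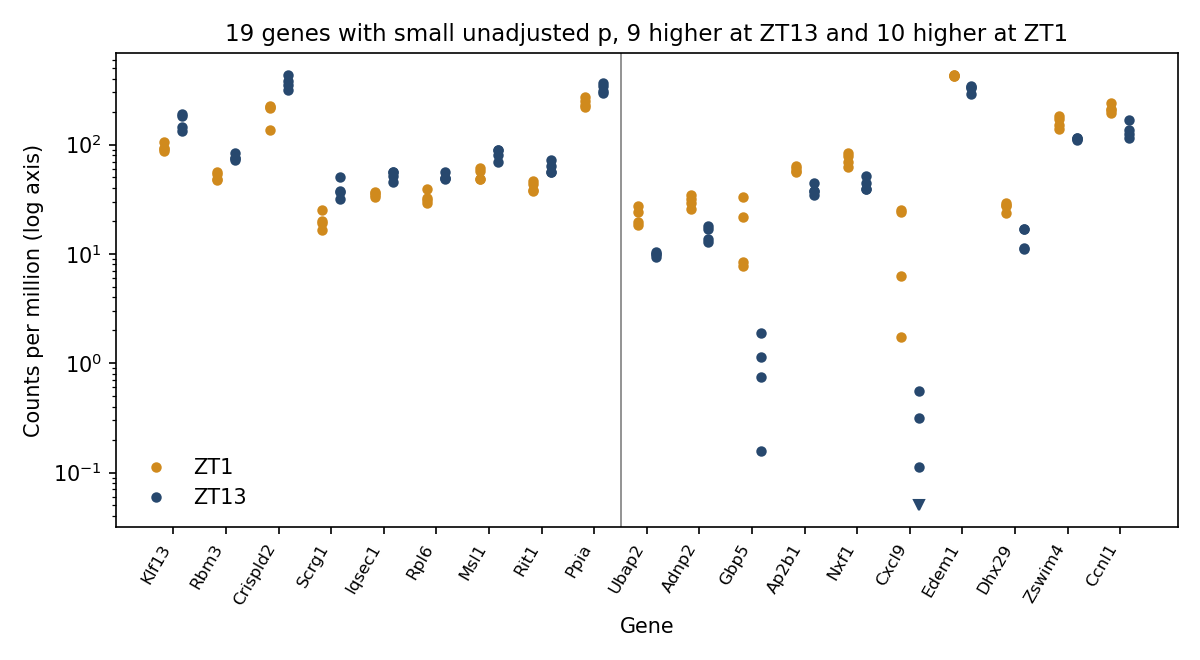
CPM (log axis) in each of the 8 libraries for 19 genes with small p, 9 with higher values at ZT13 (left of the line) and 10 with higher values at ZT1 (right). Each point is a library, and the triangle marks a library with 0 counts of Cxcl9; Gbp5 and Cxcl9 show the widest gaps, with means of 17.7 and 0.990 CPM and of 14.4 and 0.247 CPM.

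The core clock genes showed no difference past the threshold between the time points. Nfil3, a repressor of the clock output, was the most abundant of the 14 tested, at 418 ± 48.7 CPM at ZT1 and 413 ± 65.2 at ZT13 (log2 fold change -0.02 ± 0.13 SE, 95% interval from -0.30 to 0.26). Per1 stood at 23.8 ± 1.18 and 23.7 ± 11.2 CPM (-0.01 ± 0.28, interval from -0.64 to 0.62). Per2 stood at 21.1 ± 2.01 and 23.6 ± 9.23 (0.16 ± 0.27, interval from -0.43 to 0.76) and Cry1 at 60.6 ± 7.12 and 53.2 ± 3.73 (-0.19 ± 0.12). Usp2, a clock-controlled deubiquitinase, had the smallest p, with 11.6 ± 1.462 and 15.6 ± 0.630 CPM (0.42 ± 0.16; edgeR adjusted p = 0.504 over all genes and 0.289 adjusted over the list alone). Arntl (BMAL1) stood at 3.02 ± 2.01 and 3.50 ± 2.21 CPM and Dbp at 0.474 ± 0.386 and 0.516 ± 0.178 CPM. With SEs of 0.75 and 1.14 on the log2 scale, a difference of 2-fold in these genes was not detectable. Clock, Cry2, Per3, Nr1d2, Tef, Hlf and Ciart also did not pass. As lists, the genes that peak in the evening arm (10 tested) had an adjusted p of 0.167 in camera and those of the morning arm (4 tested) 0.907, and in neither list did any gene pass when adjusted over the list alone.

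**Figure D3:**
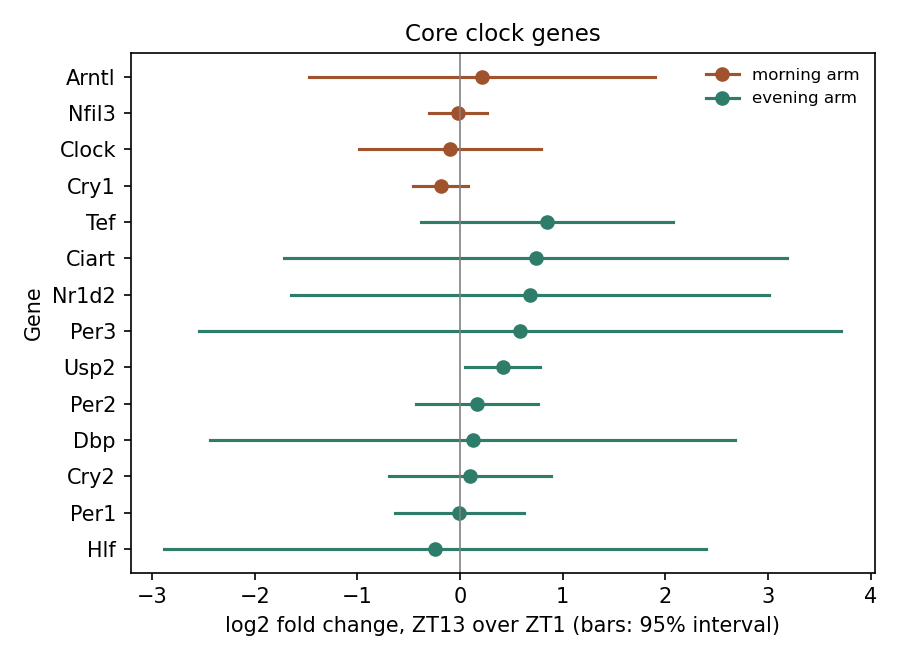
Log2 fold change of ZT13 over ZT1 for the 14 tested clock genes, with points at the edgeR estimate and bars at the 95% interval. The intervals of Nfil3 (-0.30 to 0.26), Per1 (-0.64 to 0.62) and Per2 (-0.43 to 0.76) include 0, and that of Usp2 (0.05 to 0.78) does not before adjustment.

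Of the 42 gene lists, 14 differed from the other genes in camera with the preset inter-gene correlation of 0.01, 8 with higher values at ZT13 and 6 with lower. None of the 14 passed when the correlation was estimated from these libraries (smallest adjusted p = 0.529 with an estimated correlation). In the directional test of fry 0 lists passed, while 14 passed its test for change in either direction, 6 of them among the 14 of camera. The others were the lists of multiple sclerosis drug targets, T and NK cells, glycolysis, lipid mediators, adhesion and migration, ageing, immunoregulatory and antioxidant genes. In an exact permutation test of the mean level per library 0 passed (smallest adjusted p = 0.436). The smallest p this test can give is 0.0286, so a list could pass over the 42 only if many reached it together. The preset correlation treats the members of a list as almost independent. With the number of detected genes as a covariate, 7 of the 14 lists passed in the same direction. That number separated the groups without overlap, so the covariate takes up part of any difference between the time points. Calls lost or turned with it therefore cannot be assigned to detection. Single genes passed 24 times when adjusted over the list alone, 9 times without ZT13 replicate 2, 11 times without ZT1 replicate 2 and 181 times without ZT1 replicate 3. The adjustment was made within each list and not across the 42 lists, so some passes can arise by chance. A given p also passes more readily in a list with few tested genes. With each library left out in turn 4 of the 24 passed every time: Gbp5 and Cxcl9 in the interferon-gamma list, Edem1, and Prf1 (perforin) of the T and NK cell list, at 0.391 ± 0.117 CPM at ZT1 and 0 in the 4 ZT13 libraries.

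As lists, genes of the translation and respiration machinery passed in camera with higher values at ZT13, but only at the preset correlation. All 77 tested ribosomal protein genes had positive log2 fold changes, with a median of 0.46 (camera adjusted p = 2.67e-36 with the preset correlation and adjusted p = 0.529 with an estimated correlation). Of these, 48 stood at an unadjusted p under 0.05, 0 passed over all genes and 2 adjusted over the list alone. Rpl6 stood at 33.0 ± 4.43 and 50.7 ± 3.63 CPM, and Rpl11 at 19.2 ± 5.05 and 31.8 ± 2.65. Of 77 nuclear genes of oxidative phosphorylation, 69 had positive values, with a median of 0.39 (camera adjusted p = 3.01e-23 and adjusted p = 0.529 with an estimated correlation). Ndufv3 of complex I stood at 44.8 ± 3.83 and 63.0 ± 8.82 CPM and Atp5g3 of the ATP synthase at 70.4 ± 13.9 and 98.3 ± 2.21, and 0 members passed adjusted over the list alone. The 7 tested mitochondrially encoded mRNAs gave a median of 0.14 (camera adjusted p = 0.00436 and adjusted p = 0.529 with an estimated correlation). Of these, mt-Nd2 passed adjusted over the list alone and stood at 15.9 ± 3.11 and 25.6 ± 2.02 CPM. The list did not pass among genes averaging 50 or more CPM (0.280). The share of all counts in mitochondrial mRNAs did not separate the groups, at 0.0838 ± 0.0132% and 0.0850 ± 0.0055% (exact permutation p = 0.857). The mean level per library of the ribosomal list was 4.56 ± 0.26 log2 CPM at ZT1 and 5.01 ± 0.14 at ZT13 (exact permutation p = 0.0571), with ZT1 replicate 3 at 4.91 inside the ZT13 range. Genes matched to the ribosomal list on expression, transcript length and GC content had a median log2 fold change of 0.24, and those matched to the oxidative phosphorylation list 0.22. The ZT13 libraries also held fewer detected genes (14909 ± 766 against 16891 ± 815).

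Glucocorticoid-responsive genes and specific and gelatinase granule genes were among the lists with higher values at ZT13 in camera. Of 21 tested glucocorticoid-responsive genes, 6 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00108 and adjusted p = 0.529 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 63.7 ± 15.6 and 122 ± 37.7 CPM (log2 fold change 0.94 ± 0.24 SE). Cebpd stood at 261 ± 46.2 and 377 ± 29.7 (0.53 ± 0.13) and the metallothionein gene Mt1 at 22.2 ± 6.22 and 38.2 ± 3.65 (0.79 ± 0.20). None of the 3 overlapped between the groups. The list's mean level per library was not separated by group (exact permutation p = 0.571), and its median log2 fold change over all members was 0.10. Of 17 specific and gelatinase granule genes, 15 had positive values (camera adjusted p = 0.00352 and adjusted p = 0.529 with an estimated correlation) and 0 passed adjusted over the list alone. The median was 0.14 and the mean, of opposite sign to the test, -0.18. Lcn2 stood at 6936 ± 1394 and 9801 ± 332 CPM and Ngp at 35360 ± 4231 and 44620 ± 5564, while Arg1 (arginase 1) stood at 11.3 ± 12.7 and 0.153 ± 0.305. This list no longer passed without ZT13 replicate 3 (camera adjusted p = 0.113) or with the number of detected genes, lower at ZT13, as a covariate (0.102). The mature neutrophil markers (28 tested, 16 positive, median 0.15) had a camera adjusted p of 0.00352 and adjusted p = 0.807 with an estimated correlation. Their members included the alarmins S100a8, at 25200 ± 5855 and 39080 ± 10940 CPM, and S100a9, at 27590 ± 6961 and 41790 ± 6605, and 0 passed adjusted over the list alone. The list did not pass without ZT1 replicate 1 (camera adjusted p = 0.391) or ZT13 replicate 4 (0.0515), or among genes averaging 50 or more CPM (0.0508). The immature neutrophil markers (21 tested, 14 positive, median 0.03, 0 adjusted over the list alone) had a camera adjusted p of 0.0191 and adjusted p = 0.807 with an estimated correlation. They did not pass without ZT1 replicate 3 (0.0546) or ZT13 replicate 3 (0.412), or with the covariate (0.718).

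The lists of interferon-gamma and MHC class I genes, of cytokines and chemokines and of NF-kB response genes had lower values at ZT13 in camera. Their mean levels per library overlapped between the groups (exact permutation p = 0.143, 0.229 and 0.171). In each list ZT1 replicates 2 and 3 had the highest levels. ZT1 replicates 1 and 4 lay within the ZT13 range for the first 2 lists. For NF-kB, ZT1 replicate 1 (5.30 log2 CPM) lay below every ZT13 library. Of 38 genes induced by interferon-gamma or serving MHC class I, 27 had negative log2 fold changes and 3 passed adjusted over the list alone, all lower at ZT13. The median was -0.38 (camera adjusted p = 0.00330 and adjusted p = 0.807 with an estimated correlation). Besides Cxcl9 and Gbp5, Cxcl10 stood at 46.5 ± 44.6 and 6.80 ± 1.87 CPM (log2 fold change -2.77, and -2.06 without ZT1 replicate 3), and Cd274, which encodes PD-L1, at 45.6 ± 28.2 and 17.2 ± 6.17. This list no longer passed without ZT1 replicate 3 (camera adjusted p = 0.869) or ZT13 replicate 1 (0.0900), and its direction turned among genes averaging 50 or more CPM (0.949) and with the number of detected genes, lower at ZT13, as a covariate (0.439). Of 34 cytokine and chemokine genes, 27 had negative values and 3 passed adjusted over the list alone, among them Il1a at 38.8 ± 37.6 and 4.80 ± 2.94 CPM, with 88.2 in ZT1 replicate 3. Without that library the log2 fold change of Il1a was -2.22 in place of -3.01 and its p adjusted over the list alone 0.142 in edgeR. The median was -0.46 (camera adjusted p = 0.0103 and adjusted p = 0.807 with an estimated correlation). The list did not pass without ZT1 replicate 2 (0.0720), ZT1 replicate 3 (0.869) or ZT13 replicate 4 (0.136), or among genes averaging 50 or more CPM (0.280), and its direction turned with the covariate (0.0379). Of 30 NF-kB response genes, 28 had negative values, for example Nfkbie at 90.6 ± 20.3 and 58.9 ± 11.2 CPM and Icam1 at 65.0 ± 35.5 and 31.7 ± 5.62. The median was -0.29 (camera adjusted p = 0.000761 and adjusted p = 0.807 with an estimated correlation). Adjusted over the list alone 1 gene passed. The list did not pass without ZT1 replicate 3 (0.289), among genes averaging 50 or more CPM (0.0568) or with the covariate (0.243). Its mean level per library had an SD of 0.55 log2 CPM at ZT1 and 0.08 at ZT13.

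Stress, hypoxia and cell cycle genes made up the other lists with lower values at ZT13. Of 23 hypoxia-inducible genes 16 had negative values, such as Ero1l at 250 ± 21.1 and 193 ± 21.5 CPM and Hif1a at 280 ± 59.6 and 213 ± 23.3, and 0 passed adjusted over the list alone. The median was -0.24 (camera adjusted p = 0.0103 and adjusted p = 0.529 with an estimated correlation). This was the only list of the 42 whose mean level did not overlap between the groups (5.77 ± 0.09 against 5.51 ± 0.09 log2 CPM; exact permutation p = 0.0286, adjusted 0.436). Its camera call was lost without ZT1 replicate 3 (adjusted p = 0.0857) or ZT13 replicate 2 (0.0704), among genes averaging 50 or more CPM (0.0778) and with the number of detected genes as a covariate (0.0529). Of 26 genes of the unfolded protein response 20 had negative values (median -0.18). The camera adjusted p was 0.0235, with adjusted p = 0.529 with an estimated correlation. It was 0.0667 without ZT1 replicate 3, 0.166 without ZT13 replicate 1 and 0.171 without ZT13 replicate 2. Edem1 passed adjusted over the list alone, and Ddit3, which encodes CHOP, had the opposite sign (20.3 ± 5.87 and 29.5 ± 3.15 CPM). Of 35 proliferation genes 32 had negative values (median -0.25). The camera adjusted p was 0.00108, with adjusted p = 0.807 with an estimated correlation, and 0.192 without ZT1 replicate 1. The mitotic checkpoint kinase gene Bub1 stood at 49.7 ± 15.1 and 26.2 ± 6.06 CPM and Aurka at 68.5 ± 17.2 and 42.6 ± 10.1, and 0 passed adjusted over the list alone.

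**Figure D4:**
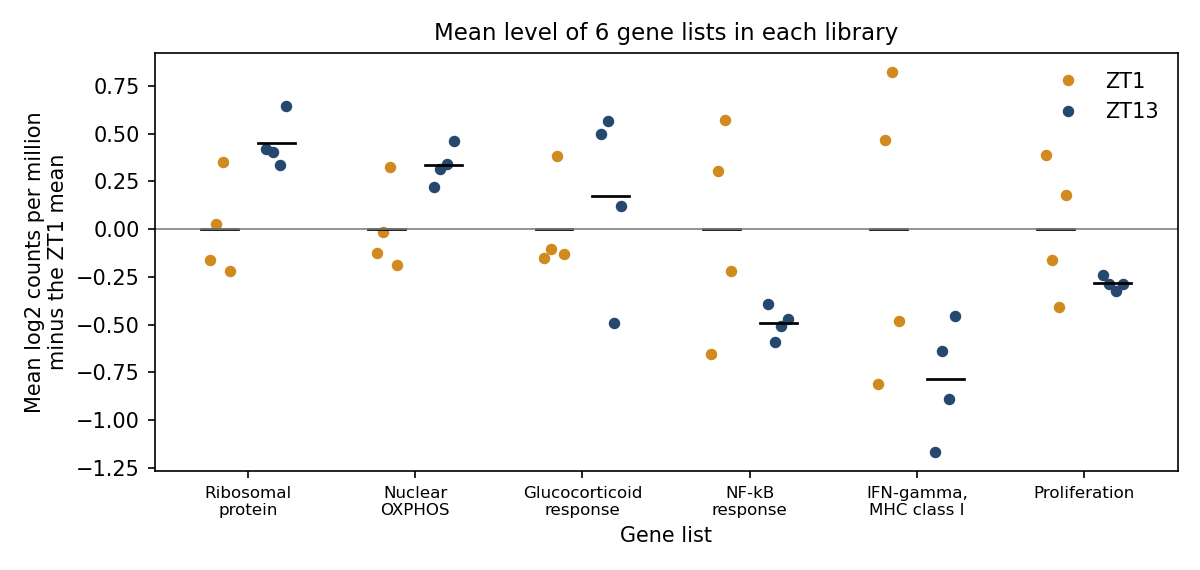
Mean log2 CPM of the members of 6 gene lists in each library, with the ZT1 mean of each list set to 0; points are libraries (4 per time point) and black lines group means. ZT13 libraries lie above the ZT1 mean for ribosomal protein genes (5.01 against 4.56 log2 CPM before centring), and the ZT1 libraries spread widely for the NF-kB and interferon-gamma lists (SDs of 0.55 and 0.77).

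Transcripts of genes listed as markers of other cell types were present in both groups, which by itself does not show that such cells were sorted. Among monocyte and macrophage markers F13a1 was the most abundant, at 1287 ± 249 and 1337 ± 215 CPM, and Ly6c2 stood at 835 ± 160 and 1166 ± 90.6 (log2 fold change 0.48 ± 0.13 SE, edgeR adjusted p = 0.403); as a list they did not pass (camera adjusted p = 0.850). The microglial list did not pass (0.565). Nor did the dendritic (0.627), T and NK cell (0.990), B and plasma cell (0.458), myelin (0.907), astrocyte and neuron (0.281), endothelial and stromal (0.959) and eosinophil, basophil and mast cell lists (0.384). The 4 tested erythroid and platelet genes passed with the preset correlation (camera adjusted p = 0.0134 and adjusted p = 0.529 with an estimated correlation), with 0 adjusted over the list alone, and did not pass with the number of detected genes as a covariate (0.222). Their levels were low: Hbb-bs stood at 0.612 ± 0.649 and 5.06 ± 6.90 CPM, with 15.4 in ZT13 replicate 4 and 0.970 to 2.48 in the other ZT13 libraries. The neutrophil effector lists of azurophil granules (camera adjusted p = 0.840), NADPH oxidase (0.207), extracellular trap formation (0.787), ageing (0.745) and adhesion and migration (0.303) did not pass either. The same held for type I interferon response (0.941), MHC class II (0.990), pattern receptors (0.0755), immunoregulatory genes (0.376), cytokine receptors (0.745), survival and apoptosis (0.392), antioxidant response (0.0814), heat shock and immediate early genes (0.745) and other clock components (0.745). Among lists that did not pass, median and mean log2 fold change differed in sign for monocyte and macrophage, T and NK cell, endothelial and stromal, MHC class II and ageing genes. The camera direction was opposite to both for adhesion and migration, extracellular trap and myelin genes. The list of targets of drugs used or studied in multiple sclerosis did not pass in camera (0.840). It passed the test of fry for change in either direction (adjusted p = 0.00283). Of its genes Ifnar1 stood at 113 ± 7.99 and 89.8 ± 3.18 CPM, the fumarate receptor gene Hcar2 at 388 ± 150 and 221 ± 58.6, and Cxcr2 at 1032 ± 90.1 and 1227 ± 97.5, with edgeR adjusted p of 0.403, 0.491 and 0.494.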

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

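Chosen after the result was seen were the tests of other cell types for the detected genes and for the interferon-gamma list, of genes of 50 or more CPM, of expression-matched lists for the interferon-gamma list, and of other splits for the edgeR count, as was the size criterion in the depth tests. Single libraries lay far from the other 3 of their group (by a gap test for outliers) in 16 of 294 groups of 4 values, 5.44%, where chance gives about 5%. The values were Crispld2 at 136 CPM in ZT1 replicate 4 (others 218 to 227), Rpl6 at 56.1 in ZT13 replicate 1, Usp2 at 16.5 and Ciart at 0.988 in ZT13 replicate 2, Msrb1 at 294 and Il18rap at 190 in ZT13 replicate 3, Wfdc17 at 1500 in ZT1 replicate 3, Arg1 at 0.611 in ZT13 replicate 1 (0 in the others), P4ha1 at 39.8 in ZT1 replicate 4, Ptprc at 1600 in ZT1 replicate 1, and Hbb-bs at 1.58 in ZT1 replicate 3 and 15.4 in ZT13 replicate 4. Mean log2 CPM of lists lay apart for glucocorticoid response (6.13) and eosinophil, basophil and mast cell genes (2.05) in ZT1 replicate 3, and for the evening-arm clock genes (0.917) and NADPH oxidase (9.47) in ZT13 replicate 3.

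The lower number of detected genes at ZT13 was a difference of -1983. Thinned to equal totals it was -1854, and -1776 without the 20 most abundant genes, beyond the SDs between libraries of 799 and 789, which argues against depth or a few abundant genes as the whole cause. The bound set beforehand also asked for no overlap and was not met, since 1 ZT13 library came to lie above the lowest ZT1 library (exact permutation p = 0.0571); that bound was too strict, because depth as the cause predicts the loss of the difference and not its separation. A general excess of other cell types at ZT1 is argued against by their 10 lists. Their median difference in mean level (0.00195 against -0.24 on the log2 scale) lay at the 98.7th percentile of expression-matched sets. It was the 71.3rd without ZT13 replicate 2, and the 99.9th for medians over genes. The matched genes were drawn independently, so these percentiles ignore correlation within lists. Of the 10, 5 had lower levels at ZT13 (1 by medians over genes). Astrocyte and neuron genes stood at -1.75 (-0.93 without ZT13 replicate 1) and endothelial and stromal genes at -0.56 (-0.21 without ZT13 replicate 3). Prf1 had no count at ZT13, though 5 of 8 T and NK cell genes had positive log2 fold changes. Mrc1 had 36 to 105 counts at ZT1 and 0, 0, 0 and 6 at ZT13, though 12 of 23 monocyte and macrophage genes were positive. An excess of these types stays open. Next to a difference in the cells themselves, which remains open and untested, loss of low-abundance transcripts during library preparation may have contributed: 903 genes with 10 or more counts in every ZT1 library had none in a ZT13 library (583 without ZT13 replicate 3; 48 genes with the groups exchanged), 22 of them in none of the 4, and a missing gene was present in 72.2% of the other ZT13 libraries, but with the groups exchanged that share was 91.4%, so it does not single out loss at ZT13.

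Ribosomal protein and oxidative phosphorylation genes had higher values at ZT13 as lists. Of 10000 lists matched on expression, transcript length and GC content, 0% had a median as high as the ribosomal list and 0% as high as the oxidative phosphorylation list. The matched genes were drawn independently of each other, while members of these lists vary together (estimated correlations of 0.585 and 0.445). A shift in a few libraries could thus lift a list above the draws, and the 0% does not exclude these properties as the cause. The matched medians of 0.24 and 0.22, against 0.46 and 0.39, leave a part of the size to a trend that genes of like length, GC content and expression share. Loss of rare transcripts is argued against, since among genes of 50 or more CPM at least 89.3% of the median relative to all genes was kept. The design tested no biological alternative other than the time point, and because these lists did not separate the libraries with an estimated correlation, a higher level at ZT13 is a hypothesis.

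Interferon-gamma-inducible genes such as Cxcl9 and Gbp5 had low values at ZT13. Of 10000 expression-matched lists 0% had a median as low, and the matched median was -0.04 against -0.38. The matched genes were drawn independently of each other, while members of this list vary together (estimated correlation 0.612). The draws therefore do not settle whether a general loss of low-abundance transcripts was the cause. Among genes averaging 50 or more CPM the direction of the list turned, without a difference from the other genes (camera adjusted p = 0.949, 18 members). That filter leaves out Cxcl9, Gbp5 and Cxcl10, so it cannot tell such a loss from a change in those genes. The loss stays open. The direction also turned with the number of detected genes as a covariate (0.439). This cannot decide the question, because that number separated the time points without overlap. Fewer antigen-presenting cells at ZT13 cannot be told apart from a change within neutrophils: the mean log2 CPM of 7 MHC class II and C1q genes differed by 0.34 (ZT13 minus ZT1), opposite to Cxcl9, but its SD between libraries of 0.88 keeps this open, and the sort on Ly6G would remove most such cells. Differences in disease course between the ZT1 mice may also contribute and were not tested.

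Chance was examined with the 35 splits of the 8 libraries into 4 and 4. For the 1160 genes at an unadjusted p under 0.05 in edgeR, 1 of the 35 splits, the real one, gave as many (highest other 1124). That is the smallest share 35 splits can give, and a mixed split came close. In that split only ZT1 replicate 3 and ZT13 replicate 3 had changed places, so it can hold part of a time-point difference. The count thus argues against chance without excluding it. For the 0 genes past the adjusted threshold in edgeR all 35 splits gave as many (highest other 0). Any split gives at least 0, so this comparison says nothing about chance. For the 256 genes called by DESeq2, 2 of the 35 splits gave as many (highest other 262), so chance was not excluded. The split with 262 was again that with ZT1 replicate 3 and ZT13 replicate 3 exchanged, and the median of the other splits was 30. For the 14 gene lists, 12 of the 35 splits gave as many (highest other 21), so chance was not excluded for their number.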

How the results depend on the processing

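Chosen after the data were seen were the settings with genes detected as a covariate, edgeR without robust estimation, the list tests among genes above 5 or 50 CPM, the exact test of list levels, DESeq2 without ZT13 replicate 3, and the adjustment over lists alone with a library left out. The count of 0 genes in edgeR stayed at 0 under each other normalization, filter and limma setting, the fold-change and 0.1 thresholds, the covariate, and with each sample left out (range 0 to 0); DESeq2 called 256 (91 higher at ZT13, 165 higher at ZT1; 90 and 91 among genes with no library at 0), and 313 (98 and 215) without ZT13 replicate 3. The cause was not tested, except that 51 of the 256 had no count at ZT13. Of 99 genes followed, 42 passed in DESeq2 and 0 in the other settings in which single genes were followed, which do not include DESeq2 without ZT13 replicate 3. The share of genes at an unadjusted p under 0.05 that were higher at ZT13 was 47.2%, against 34.0% with library totals, 49.9% with DESeq2 size factors and 55.3% with upper-quartile factors. The replicate numbers do not pair the samples: same-numbered libraries correlated at -0.087 to 0.016 and 0 of 4 correlated best with their own number; with the replicate block 0 genes and 16 lists passed, and with the library-name replicate block 0 genes.

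In place of 14 lists, 0 passed with an estimated correlation, 0 with the directional test of fry (14 with its test for either direction), 0 with the exact test and 7 among genes averaging 50 or more CPM (fewer genes tested), 10 to 16 with a sample left out, and 14 to 16 under other normalizations. The exact test had little room to pass any list, since its smallest possible p is 0.0286 before adjustment. Without ZT1 replicate 3, 8 of the 14 passed and 2 other lists. The ribosomal list had adjusted p = 0.529 with an estimated correlation and 0.278 with fry, as did oxidative phosphorylation (0.529 and 0.278). With a sample left out they ranged from 1.05e-49 to 1.72e-24 and from 4.94e-39 to 6.42e-16. The direction of the cytokine list turned with the covariate (adjusted p = 0.0379), and that of the interferon-gamma list with the covariate (0.439) and at 50 or more CPM (0.949). With the covariate the specific granule (0.102), NF-kB (0.243), hypoxia (0.0529), immature neutrophil (0.718) and erythroid lists (0.222) did not pass. The covariate separated the groups without overlap, so these changes do not tell detection from time point. At 50 or more CPM the cytokine (0.280), NF-kB (0.0568), hypoxia (0.0778), mature neutrophil (0.0508) and mitochondrially encoded lists (0.280) did not, nor the cytokine list in the 5 CPM filter (0.0988). The cause was not tested.

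Of the 99 log2 fold changes 14 changed sign somewhere, none among the 19 genes named for their small p and none past the edgeR threshold over all genes; the cause was not tested. Of the 14, Il1a passed in DESeq2 (adjusted p = 0.0445) and adjusted over its list alone in edgeR (0.0493). With a sample left out Arntl ranged from -0.26 to 0.53, Clock from -0.38 to 0.11, Nfil3 from -0.13 to 0.0659, Per1 from -0.38 to 0.18, Per2 from -0.0151 to 0.35, Cry2 from -0.17 to 0.36, Hlf from -1.55 to 0.17, Dbp from -0.29 to 0.55, Nr1d2 from 0.19 to 1.09, Arg1 from -12.31 to -5.37, Il1a from -3.34 to -2.22, F13a1 from -0.0598 to 0.16, Nkg7 from -0.31 to 0.40 and Itgam from -0.0054 to 0.0346. With the covariate Clock was 0.76, Nfil3 0.038, Per1 0.51, Per2 -0.27, Cry2 -0.0121, Arg1 0.19 and Il1a 0.13. With upper-quartile factors Nfil3 was 0.0019 and Per1 0.0152, with the 5 CPM filter 0.0027 and 0.02, with no filter Itgam -0.0020, and with library totals F13a1 -0.0106 and Itgam -0.0425. With limma-voom Nr1d2 was -1.32 and Nkg7 0.0227, and with quality weights Nr1d2 -0.54 and Per2 -0.0091. With the replicate block Nr1d2 was -0.0026 and Nkg7 0.033, and with the library-name replicate block Nr1d2 -0.73.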

Other observations

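Apart from the fits with a library left out, none of the tests given here was chosen after its result was seen. The genes follow the rule for named genes. Of 19 genes of lipid mediator pathways 10 had positive log2 fold changes, and the list did not pass (camera adjusted p = 0.0755). Adjusted over the list alone 3 genes passed: Fpr2, a formyl peptide receptor, at 152 ± 30.9 CPM (SD, n = 4) at ZT1 and 223 ± 10.2 at ZT13, Alox5ap, the 5-lipoxygenase activating protein, at 457 ± 108 and 672 ± 49.2, and Alox15 at 0.828 ± 0.102 and 3.86 ± 2.29. None passed over all genes in edgeR (adjusted p from 0.382 to 0.403), and the 3 genes passed in DESeq2 (adjusted p = 0.0207, 0.0407 and 0.00453). With each library left out in turn, they passed adjusted over the list alone in 3, 2 and 3 of 8 fits. In glycolysis (camera adjusted p = 0.0755) the phosphofructokinase genes Pfkp, at 175 ± 10.7 and 130 ± 14.2 CPM, and Pfkl, at 140 ± 6.91 and 104 ± 19.1, had lower values at ZT13, and 1 of 20 genes, Pfkp, passed adjusted over the list alone. Pfkp did so in 2 of 8 fits with a library left out.

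Some genes of lists that did not pass had values without overlap between the groups. Lilrb4a, an inhibitory receptor of myeloid cells, stood at 405 ± 126 CPM at ZT1 and 181 ± 38.0 at ZT13 (edgeR adjusted p = 0.256 over all genes and 0.0219 adjusted over its list alone), and Slfn4, a myeloid interferon-inducible gene, stood at 689 ± 318 and 293 ± 70.9 CPM (adjusted p = 0.385), while the type I interferon list as a whole did not pass. Trf (transferrin), listed among myelin genes but expressed by other cells too, stood at 503 ± 49.4 and 343 ± 59.9 CPM (adjusted p = 0.333 over all genes and 0.0133 adjusted over its list alone). With each library left out in turn, Lilrb4a passed adjusted over its list alone in 4 of 8 fits and Trf in 6.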
